A study of Mus musculus with 12 samples.

How the data were processed

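Bulk RNA sequencing of mouse liver was analysed in 4 groups formed by 2 genotypes and 2 feedings. Floxed mice (FLOX) carried loxP-flanked Lpcat3, and Cre mice (LKO) carried the floxed gene together with a cre transgene. Each genotype was given either control feeding (NC) or the NIAAA model (ALD), a mouse protocol of alcoholic liver injury by ethanol. The words diet, NIAAA diet and NIAAA feeding below stand for the whole model. The diet effect is the difference between the whole NIAAA model and control feeding, and the groups do not separate any steps within the model. All 12 samples are labelled as male C57BL/6 mice. Of these, 11 libraries were used, and LKO-NC replicate 3 was not analysed here. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. FLOX-ALD replicate 1 differed from replicates 2 and 3 in sex-specific transcripts, so the 3 did not all come from 1 animal.

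Per the labels' protocols, mRNA was taken with a KAPA stranded mRNA kit and libraries were made with a SMARTER mRNA library kit. The submitters' processing notes list cutadapt, FastQC, HISAT2, StringTie and edgeR without versions, and genome build mm10. The deposited gene and transcript tables hold estimated counts, which were already whole numbers and were used without rounding. Each of the 55401 gene values equalled the sum of the gene's transcripts in the table of 142604 transcripts. The authors also deposited FPKM values per gene and transcript, which were tested as an alternative. For transcripts with a count of at least 200, these FPKM values lay within 0.45% of count divided by length and by 1 factor per library. Counting parameters and the strand setting are not given in the sources used here, so overlapping genes on opposite strands, near-identical paralogs and the assignment of reads to a gene's transcripts remain uncertain. The exons removed by cre are not stated. Gene positions are those of the mm10 annotation, in which 55141 of the gene identifiers were found.

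Total estimated counts ran from 39.1 to 73.6 per library in units of 1e6. Of the genes, 22731 had a count of 0 in all libraries, and 19014 passed the filter on low counts (filterByExpr of edgeR 4.0.16, minimum count 10, minimum total 15, in at least 2 libraries). Counts were scaled by trimmed mean of M-values (TMM) and fitted with edgeR's robust quasi-likelihood model, with 1 mean per group, 7 residual degrees of freedom and 5.51 prior degrees of freedom. The common biological coefficient of variation was 42.2%. There were 5 contrasts, 4 between groups and 1 for the interaction of diet and genotype. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. "edgeR adjusted p" below is this value. Fold changes are on the log2 scale, and their standard error (SE) is the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled counts per 1e6 (CPM), as mean ± SD. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used for the other tests.

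The design, the alternatives, the rule for named genes and 45 gene lists were fixed before the data were examined. The lists comprised 13 sets of cell type markers and 32 liver pathways and gene classes, with 943 entries of which 908 were tested. In some lists few tested members had a mean over 1 CPM across the libraries. These were 5 of 11 neutrophil, 2 of 14 T and NK cell and 5 of 11 B and plasma cell markers. Medians of these lists in every comparison rest largely on genes of low counts. Lists were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 45 lists of a comparison ("camera adjusted p"). Camera was repeated with a correlation estimated from the residuals of each list, and fry was run as a self-contained test. The lists are also described by the count of members past the threshold over all genes, the count adjusted over the list alone, and the median log2 fold change. Where a member had a count of 0 in every library of a group, the median was also computed with that member at a bound of 3 counts per library.

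Named genes were Lpcat3 and Nampt in every comparison, and per comparison up to 6 higher and 6 lower genes of largest log2 fold change among those past the threshold whose libraries did not overlap between the groups, with a mean log2 CPM of at least 1 and no clone-like symbol. Up to 3 higher and 3 lower members past the threshold were added from each list with at least 2 such members or a camera adjusted p under 0.05. Where a list had none, up to 2 members of largest mean CPM could be given as values. The condition on overlap was dropped for the interaction. List members that passed only when adjusted over the list alone, and any other gene, were named after their values were seen.

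The design had assumed 12 libraries of read counts. The deposited values were estimated counts of 11 libraries, and the same tests were applied to them. The alternatives were other scaling factors, other filters on low counts, a non-robust fit, DESeq2, limma voom with quality weights, limma trend on log2(FPKM + 1), a scale that understates the change of low genes, stricter thresholds, fits of only the 2 groups compared, a replicate block and leaving out each library in turn. Leaving out FLOX-ALD replicate 1 together with LKO-NC replicate 1, and leaving out the mitochondrially encoded genes, were chosen after seeing the data. With 1 LKO-NC library left out, the remaining one was assumed to vary like the other groups.

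The test was checked on simulated data drawn from the gene means, spreads and library sizes of the real samples. In each comparison 100 genes were changed 2-fold and 100 genes 4-fold. In the diet comparison of floxed mice, simulated over 18392 genes, 5% of the 2-fold and 53% of the 4-fold changes were recovered, with 4 false calls. In the diet comparison of Cre mice, over 18326 genes, 3% and 46% were recovered with 3 false calls. In the genotype comparison on control feeding, over 18295 genes, 2% and 34% were recovered with 1 false call. In the genotype comparison on NIAAA feeding, over 18333 genes, 3% and 47% were recovered with 2 false calls. Changes of 2-fold were therefore mostly not detectable with these libraries. A simulated unchanged list reached a camera p of 0.0129 in the diet comparison of floxed mice. In the diet comparison of Cre mice and the genotype comparisons on control and NIAAA feeding, this p was 0.472, 0.205 and 0.965. Simulated genes varied independently of each other, so the simulation cannot check camera's preset correlation for the real lists.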

Results

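Liver transcriptomes of floxed and Cre mice on control or NIAAA feeding were compared. According to its title, the series asked what hepatic LPCAT3, and with it NAMPT, does in alcoholic liver injury. FLOX-NC, FLOX-ALD and LKO-ALD held 3 libraries each and LKO-NC held 2. Total counts, in units of 1e6, were 62.8, 47.8 and 50 in FLOX-NC, 42.6 and 49.4 in LKO-NC, 71.9, 51.9 and 39.1 in FLOX-ALD, and 49.2, 58.0 and 73.6 in LKO-ALD.

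Lpcat3 encodes the acyltransferase that places polyunsaturated fatty acids into lysophospholipids (ENSMUSG00000004270, chromosome 6, 124663027 to 124704418, + strand, mm10). As the targeted gene it was read in every library first. Its level was 103, 87.1 and 101 CPM in FLOX-NC, 29.2 and 37.2 CPM in LKO-NC, 37.9, 43.2 and 30.5 CPM in FLOX-ALD, and 10.8, 15.4 and 9.80 CPM in LKO-ALD. On each feeding, every Cre library lay below every floxed library, as the genotype labels state. The group means were 97.2 ± 8.80 CPM in FLOX-NC (SD, n = 3), 33.2 ± 5.63 in LKO-NC (n = 2), 37.2 ± 6.4 in FLOX-ALD (n = 3) and 11.98 ± 2.99 in LKO-ALD (n = 3). The genotype difference of Lpcat3 was −1.55 (SE 0.255) on control feeding and −1.63 (SE 0.222) on NIAAA feeding. Neither passed adjustment over all genes (edgeR adjusted p = 0.176 and 0.132, unadjusted p = 4.68e-05 and 6.93e-06), while DESeq2 called both (adjusted p = 5.34e-05 and 1.34e-06). The second passed in edgeR without FLOX-ALD replicate 3 (adjusted p = 0.0374) or LKO-ALD replicate 2 (0.0483). Lpcat3 also fell on the NIAAA diet, by 1.39 on the log2 scale in floxed mice (SE 0.220, edgeR adjusted p = 0.0389) and by 1.47 in Cre mice (SE 0.239, edgeR adjusted p = 0.0303). In floxed mice the call was lost without FLOX-NC replicate 1, 2 or 3 (adjusted p = 0.172, 0.101 and 0.131) and without FLOX-ALD replicate 1 or 3 (0.0766 and 0.0655). In Cre mice it was lost without LKO-NC replicate 1 or 2 (adjusted p = 0.0824 and 0.071) and without LKO-ALD replicate 1 or 3 (0.12 and 0.0736). The diet effect on Lpcat3 did not differ detectably between the genotypes (interaction −0.09, SE 0.324, edgeR adjusted p = 0.954). The interaction was 0.09, 0.03 and 0.08 without LKO-NC replicate 2, FLOX-ALD replicate 2 and LKO-ALD replicate 3. Which Lpcat3 transcript was assigned the reads varied between libraries. Transcript ENSMUST00000135516 had counts of 3689, 2760 and 3651 in FLOX-NC and of 0 and 0 in LKO-NC. It had 1646, 0 and 382 in FLOX-ALD and 467, 788 and 0 in LKO-ALD. The effect of this assignment on the Lpcat3 values was not tested.

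Nampt, the rate-limiting enzyme of NAD salvage from nicotinamide (ENSMUSG00000020572, chromosome 12, 32819545 to 32853349, + strand), was measured at 101 ± 20.8 CPM in FLOX-NC (n = 3), 74.3 ± 8.11 in LKO-NC (n = 2), 40.1 ± 4.65 in FLOX-ALD (n = 3) and 89.7 ± 33.6 in LKO-ALD (n = 3). All 3 FLOX-ALD libraries lay below all libraries of the other groups. The diet difference was −1.34 (SE 0.264) in floxed mice and 0.27 (SE 0.292) in Cre mice, and the latter was −0.08 without LKO-ALD replicate 3. The genotype difference was −0.45 (SE 0.293) on control feeding and 1.16 (SE 0.263) on NIAAA feeding, and the interaction was 1.61 (SE 0.396). None passed over all genes (edgeR adjusted p = 0.0756, 0.66, 0.828, 0.371 and 0.498 in this order). DESeq2 called the diet difference in floxed mice and the genotype difference on NIAAA feeding (adjusted p = 0.000505 and 0.0178). Adjusted over the list alone, the NAD synthesis and salvage list of 22 tested genes, Nampt passed in the diet comparison of floxed mice (adjusted p = 0.0038), in the genotype comparison on NIAAA feeding (0.017) and in the interaction (0.032). These contrasts all contain the FLOX-ALD libraries, so the passes are not independent. Adjustment over the list alone was not repeated without single libraries. Over all settings the 3 differences ran from −1.487 to −1.195, from 0.831 to 1.325 and from 1.292 to 1.771.

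**Figure D1:**
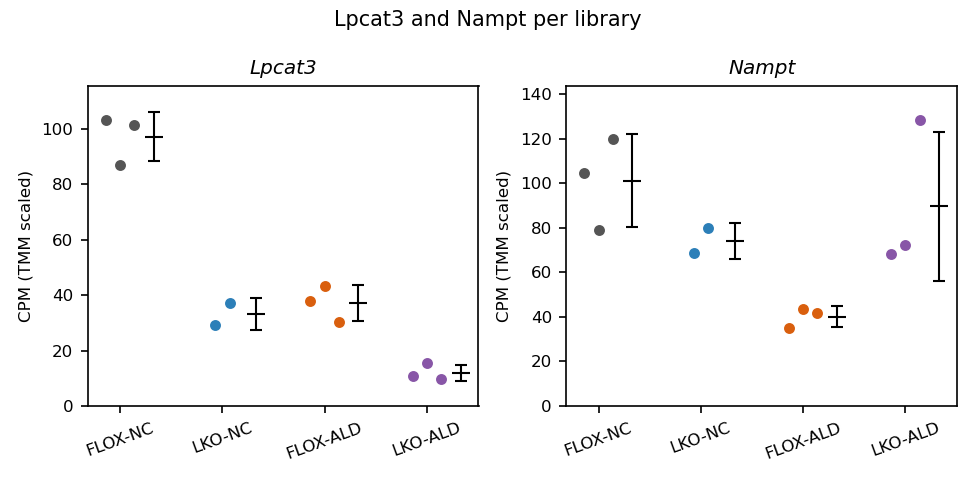
CPM (TMM scaled, linear axes from 0) of Lpcat3 and Nampt in each library, by group; the points are libraries and the bars give the mean and SD (n = 3, and n = 2 in LKO-NC). Lpcat3 was highest in FLOX-NC (97.2 CPM) and lowest in LKO-ALD (11.98 CPM), and Nampt was lowest in FLOX-ALD (40.1 CPM).

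Libraries of a group differed in ways that the groups did not explain. FLOX-ALD replicate 1, labelled male, had 772 CPM of Xist, the transcript of the inactive X chromosome, against at most 2.95 CPM in the other libraries. It had 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose summed level was 135 to 227 CPM elsewhere. It lay at the female extreme of the 11 libraries for 41 of 50 tested members of the male- and female-biased liver gene lists. The share of counts from mitochondrially encoded genes was 12.4% ± 0.518 in FLOX-NC (n = 3), 20.3% ± 7.02 in LKO-NC (n = 2), 20.6% ± 6.85 in FLOX-ALD (n = 3) and 14.0% ± 0.952 in LKO-ALD (n = 3), with 25.3% in LKO-NC replicate 1, 22.3% in FLOX-ALD replicate 2 and 26.4% in FLOX-ALD replicate 3. By rank correlation over genes, each FLOX-ALD library lay nearest to a library of another group, and LKO-NC replicate 2 lay nearest to FLOX-NC replicate 1. No pair of replicates differed by as little as sampling noise (chi-square per degree of freedom 41.7 to 876).

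**Figure D2:**
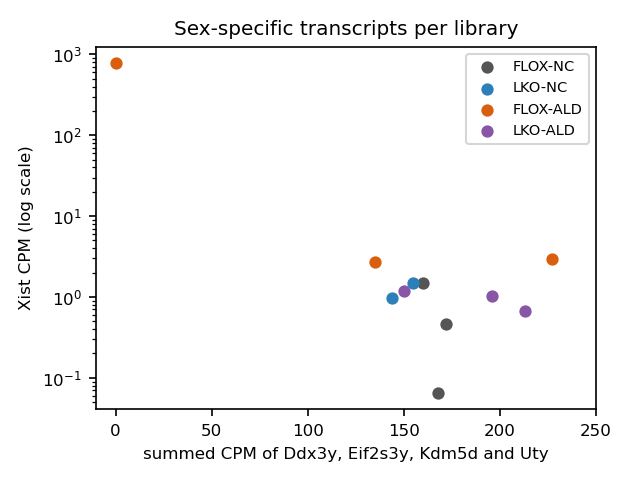
Xist level (CPM, log axis) against the summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty (linear axis); each point is 1 library, coloured by group. FLOX-ALD replicate 1 stands alone at 772 CPM of Xist and 0 CPM of the Y-linked genes.

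The effect of the NIAAA diet in floxed mice was examined first (FLOX-ALD against FLOX-NC). Pck1, the rate-limiting enzyme of gluconeogenesis, fell from 3415 ± 537 to 1008 ± 199 CPM (n = 3 and 3, log2 fold change −1.76, SE 0.302, edgeR adjusted p = 0.0428). Without single libraries its adjusted p ran from 0.0477 to 0.179, and the call held only without FLOX-ALD replicate 2. All other 19 tested genes of the gluconeogenesis and glucose handling list stayed short of the threshold, while 5, Pck1 included, fell when adjusted over the list alone, among them Sds (−1.21, SE 0.229), the transcriptional coactivator Ppargc1a (−1.28, SE 0.263) and G6pc (−2.26, SE 0.708). That list had a median of −0.37 (camera adjusted p = 3.12e-07; adjusted p = 0.277 with an estimated correlation). Periportal hepatocyte genes had a median of −0.48 over 22 genes, with 1 called, Pck1, and 8 lower when adjusted over the list alone, including Gls2 and Cyp2f2 (camera adjusted p = 1.31e-09; adjusted p = 0.277 with an estimated correlation). In fatty acid synthesis and desaturation, 21 of 22 genes had negative values with a median of −0.98 (camera adjusted p = 1.31e-09; adjusted p = 0.355 with an estimated correlation). None of its members was called over all genes, and 5 fell when adjusted over the list alone, the ATP citrate lyase gene Acly (−1.90, SE 0.549), the desaturase gene Scd1 (−1.59, SE 0.451), Pklr, Elovl5 and Elovl2. The NAD list had a median of −0.52, with 0 called and 2 higher (Nnmt and Nt5e) and 2 lower (Nampt and Qprt) when adjusted over the list alone (camera adjusted p = 0.00444; adjusted p = 0.411 with an estimated correlation). Some medians moved by over 1.5 times without 1 library, namely fatty acid synthesis to −0.65 without FLOX-NC replicate 3, periportal genes to −0.74 and gluconeogenesis to −0.63 without FLOX-ALD replicate 1, and gluconeogenesis to −0.68 without FLOX-ALD replicate 2.

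Of all 19014 genes, 42 were called by edgeR in this comparison, 9 higher and 33 lower, each at least 2-fold. The immediate-early phosphatase gene Dusp1 fell from 49.0 ± 18.3 to 9.44 ± 2.86 CPM (log2 fold change −2.38, SE 0.406, edgeR adjusted p = 0.0428). Zfand4 (−1.84, SE 0.231), the pro-apoptotic gene Bmf (−1.99, SE 0.292), Cabyr (−2.39, SE 0.416) and the class I MHC gene H2-Q1 (−2.69, SE 0.400) also fell. The acyltransferase gene Acnat2 rose from 12.3 ± 3.35 to 131 ± 58.6 CPM (3.41, SE 0.392, edgeR adjusted p = 0.0077). Slc16a5 rose by 2.42 (SE 0.409), Gdf10 by 1.89 (SE 0.306), the tubulin gene Tuba1c by 1.36 (SE 0.237) and Ildr2 by 1.13 (SE 0.187). Jade1 rose by 3.13 (SE 0.322, edgeR adjusted p = 0.00508) together with a shift in which of its transcripts was assigned the reads, and on FPKM values its difference was 1.61 (limma adjusted p = 0.0504). The count was 3, 3 and 2 without FLOX-NC replicates 1, 2 and 3, and 15, 146 and 25 without FLOX-ALD replicates 1, 2 and 3, against 595 by DESeq2 and 64 by limma voom. Of the 13 called genes named here for this comparison, Lpcat3 aside, 1, 2, 1, 5, 11 and 6 passed in those 6 fits, and all 13 had the same direction in each. Dusp1 and Ighm passed in 0 of the 6.

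Among cell type markers and stress genes in floxed mice, the immunoglobulin heavy chain gene Ighm fell from 9.50 ± 4.41 to 2.07 ± 0.589 CPM (log2 fold change −2.19, SE 0.385, edgeR adjusted p = 0.0428). It was the 1 called gene of 11 B and plasma cell markers, of which 2 fell when adjusted over the list alone (median −0.79, camera adjusted p = 0.000201; adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes had 24 of 29 negative values, 0 called and 7 lower when adjusted over the list alone, with a median of −0.41 (camera adjusted p = 2.12e-05; adjusted p = 0.535 with an estimated correlation). Neutrophil markers had a median of 2.78 over 11 genes, the same with 1 member at its bound, and 0 called. S100a8, Cxcr2 and Lcn2 rose when adjusted over the list alone (camera adjusted p = 0.000237, and 0.535 with an estimated correlation). Of the 11, 5 had a mean over 1 CPM. Lcn2 is also on the acute phase list, and its level was 33.0 ± 18.8 CPM in FLOX-NC and 1386 ± 1950 CPM in FLOX-ALD. Acute phase genes, the liver's secreted inflammatory proteins, had 24 of 26 positive values, 0 called over all genes or adjusted over the list alone, and a median of 1.33 (camera adjusted p = 3.19e-06; adjusted p = 0.535 with an estimated correlation). Without FLOX-ALD replicate 1 that median was 0.43 and the call was lost (camera adjusted p = 0.111). Genes of the endoplasmic reticulum stress response had 19 of 20 positive values, 0 called in either adjustment and a median of 0.90 (camera adjusted p = 0.000305; adjusted p = 0.535 with an estimated correlation; lost at 0.0693 without FLOX-ALD replicate 3). Male-biased liver genes had a median of −1.56 with 0 called and 7 lower when adjusted over the list alone, and female-biased genes a median of 5.38, the same with 4 members at their bound, with 0 called and 10 higher when adjusted over the list alone (camera adjusted p = 3.64e-17 and 3.19e-06; adjusted p = 0.351 and 0.535 with an estimated correlation). Without FLOX-ALD replicate 1, the library with female-type sex transcripts, these medians were −1.17 and 1.28. The medians were −1.22 for B cell markers without that library and −0.26 for interferon-stimulated genes without FLOX-ALD replicate 3. Hepatocyte markers, not called, had a mean log2 CPM of 11.93, 11.87 and 11.92 in FLOX-NC and of 11.89, 11.56 and 11.57 in FLOX-ALD. FLOX-ALD replicates 2 and 3 had 22.3% and 26.4% mitochondrial counts. Camera called sinusoidal endothelial and stellate cell markers higher, with medians of 0.14 to 0.53 and 0.013 to 0.90 without single libraries. Both lost their call without FLOX-ALD replicate 2 (camera adjusted p = 0.271 and 0.887).

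In Cre mice the diet effect (LKO-ALD against LKO-NC) included called genes among B cell, Kupffer cell and dendritic cell markers and interferon-stimulated genes, with lower values in most members of these 4 lists. Neutrophil markers had a median of 0.05 and a mean of −0.46 with 0 called in either adjustment (camera adjusted p = 0.592). All 11 tested B and plasma cell markers had negative values (median −2.53), and 4 fell, among them the B cell receptor partner Cd22 (from 2.55 ± 1.05 CPM, n = 2, to 0.224 ± 0.0641, n = 3; log2 fold change −3.49, SE 0.522, edgeR adjusted p = 0.0229), Ighm (−2.54, SE 0.413) and Ighd (−2.90, SE 0.551). Of 15 Kupffer cell and macrophage markers, 14 had negative values (median −1.47), and 2 fell, the Kupffer cell lectin Clec4f (from 107 ± 41.0 to 27.9 ± 10.3 CPM; −1.94, SE 0.389) and Cd68 (−2.44, SE 0.463). Of 29 interferon-stimulated genes, 28 had negative values (median −1.39), and 4 fell, among them Mx1 (−3.21, SE 0.544), Oas2 (−2.33, SE 0.458) and Ifi27l2a (−2.21, SE 0.367). The class II MHC genes H2-Aa (−1.81, SE 0.33) and H2-Eb1 (−1.66, SE 0.29) were the 2 called of 14 dendritic cell markers (median −1.25). Adjusted over the list alone, 8 B cell, 11 Kupffer cell, 16 interferon-stimulated and 8 dendritic genes fell. Camera called the 4 lists (adjusted p = 5.62e-11, 2.65e-08, 7.08e-15 and 4.98e-07 for B cell, Kupffer cell, interferon and dendritic genes), and none held (adjusted p = 0.111, 0.668, 0.588 and 0.641 with an estimated correlation). Fry called the B and plasma cell list (fry adjusted p = 0.00734) but not the Kupffer cell, interferon and dendritic lists (0.23, 0.0536 and 0.0936). Without LKO-NC replicate 1, the library with 25.3% mitochondrial counts, all 4 lists stayed called by camera, with medians of −1.96, −1.07, −0.87 and −0.75, while Oas2 was −1.47 and not called (edgeR adjusted p = 0.409). Of 14 T and NK cell markers, 2 had a mean over 1 CPM, as had 5 of the 11 B and plasma cell markers. The T and NK cell list had 13 of 14 negative values (median −1.15), with 0 called and 1 lower when adjusted over the list alone (camera adjusted p = 0.00312, and 0.771 with an estimated correlation). Infiltrating monocyte markers had 12 of 14 (median −1.13) with 0 called and 2 lower when adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.812 with an estimated correlation). Without LKO-NC replicate 1 both lost their camera call, with medians of −0.86 and −0.07 (camera adjusted p = 0.0932 and 0.414), and the monocyte list also lost it without LKO-ALD replicate 1 (−0.81, 0.11) or 2 (−1.06, 0.0973).

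**Figure D3:**
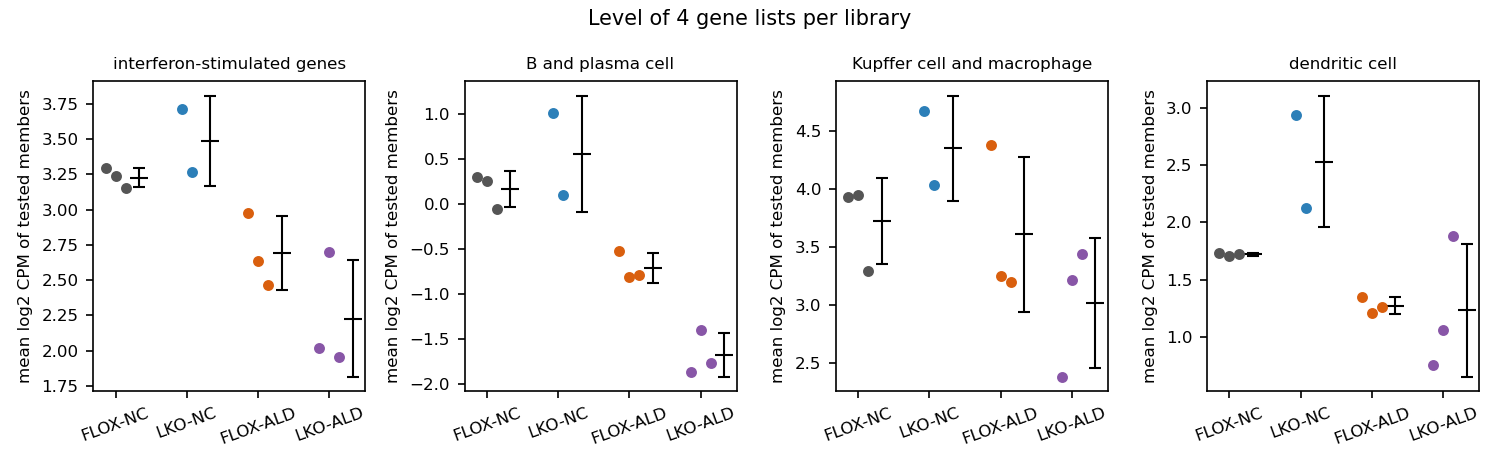
Mean log2 CPM of the tested members of 4 gene lists (interferon-stimulated, 29 genes; B and plasma cell, 11; Kupffer cell and macrophage, 15; dendritic cell, 14) in each library, by group; points are libraries and bars give the mean and SD (n = 3, and n = 2 in LKO-NC), and the axes differ between panels and do not start at 0. For B and plasma cell markers, LKO-ALD (−1.87, −1.40 and −1.77) lies below all other libraries, and LKO-NC replicate 1 is the highest library in all 4 panels.

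Single genes of several other lists were called for the diet in Cre mice. Cyp2b10, the classical target of the nuclear receptor CAR, rose from 0.146 ± 0.206 CPM (counts of 0 and 14) to 102 ± 23.4 CPM (log2 fold change 9.41, SE 1.71, edgeR adjusted p = 0.0495). Over all settings its log2 fold change ran from 5.43 to 15.45. Without single libraries it passed in 0 of 5 fits (adjusted p from 0.068 to 0.35), and without LKO-NC replicate 2 the remaining control library had a count of 0. Nr1i2, which encodes the nuclear receptor PXR, fell (−1.42, SE 0.262). These were the 2 called of 23 genes of xenobiotic metabolism by CAR and PXR, with 2 higher and 1 lower when adjusted over the list alone (median 0.68, camera adjusted p = 0.00312; adjusted p = 0.771 with an estimated correlation), and the camera call was lost without LKO-NC replicate 1 (median 0.56, camera adjusted p = 0.0572). Serpina3m, an acute phase gene, rose from 128 ± 59.5 to 1020 ± 578 CPM (2.99, SE 0.58), and the glutathione transferase gene Gstt3 rose by 3.32 (SE 0.664). Abca1, the cholesterol exporter induced by LXR, rose by 1.85 (SE 0.376). Abca1 and Lpcat3, which fell, are both on the LXR target list, which camera did not call here. The mean log2 CPM of its 18 tested members was 5.44, 5.51 and 5.07 in LKO-ALD and 5.72 and 5.75 in LKO-NC. In floxed mice camera called LXR targets lower, with medians of −0.44 to −0.18 without single libraries. Fry called them there too (fry adjusted p = 0.0384), but they did not hold with an estimated correlation. Of the 26 tested lysophospholipid acyltransferases and phospholipases, Lpcat3, Lpcat2 (−2.08, SE 0.44) and Pla2g6 (−1.31, SE 0.223) fell, 3 were higher and 4 lower when adjusted over the list alone, and the list was not called (median −0.05, camera adjusted p = 0.759). Nfkb2 (−1.58, SE 0.277) and Nfkbia (−1.18, SE 0.201) were the 2 called of 28 cytokine and NF-kB target genes, with 6 lower when adjusted over the list alone (median −0.77, camera adjusted p = 0.000105; adjusted p = 0.771 with an estimated correlation); that median was 0.38 without LKO-NC replicate 1 (camera adjusted p = 0.285) and −1.15 without LKO-NC replicate 2. Endoplasmic reticulum stress genes were positive in 20 of 20, with 0 called in either adjustment (median 1.22, camera adjusted p = 4.85e-05; adjusted p = 0.874 with an estimated correlation). Without LKO-NC replicate 1 their median was 0.70 and the call was lost (camera adjusted p = 0.0554), and it was 1.93 without LKO-NC replicate 2 and 0.51 without LKO-ALD replicate 3. Acute phase genes had a median of 1.11 with 1 called in either adjustment, Serpina3m (camera adjusted p = 0.00178; adjusted p = 0.874 with an estimated correlation), lost at 0.0614 without LKO-ALD replicate 3. Fatty acid synthesis genes had a median of −0.62 with 0 called and 1, Gpam, lower when adjusted over the list alone (camera adjusted p = 0.00513; adjusted p = 0.874 with an estimated correlation). Without LKO-NC replicate 2, LKO-ALD replicate 2 and LKO-ALD replicate 3 that median was −0.14, −1.02 and −0.38, and the call was lost in the first and last (camera adjusted p = 0.475 and 0.103).

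In all, edgeR called 182 genes for the diet in Cre mice, 56 higher and 126 lower, each at least 2-fold. The most reduced by the rule for named genes were Fbf1 (−3.62, SE 0.511), whose reads were assigned to different transcripts within groups, Rasa4 (−3.42, SE 0.435), the potassium channel gene Kcna2 (−3.40, SE 0.503), the sarcomere gene Myom1 (−3.24, SE 0.324), the macrophage-expressed galectin gene Lgals3 (−3.11, SE 0.558) and the antisense transcript Tbx3os1 (−3.06, SE 0.484), which is uncertain where counting ignored strand. Myom1 had the smallest edgeR adjusted p, 0.00475. Fgf2 was called higher by 5.38 (SE 0.608) from counts of 7 and 2 in LKO-NC (on FPKM values 0.36, limma adjusted p = 0.283), Zfp324 by 2.78 (SE 0.593) and Mcrip1 by 2.13 (SE 0.411). The count was 12 and 129 without LKO-NC replicates 1 and 2, and 6, 138 and 9 without LKO-ALD replicates 1, 2 and 3, against 1470 by DESeq2 and 647 by limma voom. Of the 28 called genes named here for this comparison, Lpcat3 aside, 2, 17, 3, 15 and 4 passed in those 5 fits, and all 28 kept their direction. Lgals3 was −1.43 without LKO-NC replicate 1 (edgeR adjusted p = 0.409), and Zfp324, Gstt3, Clec4f, Lpcat2 and Cyp2b10 passed in 0 of the 5.

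**Figure D4:**
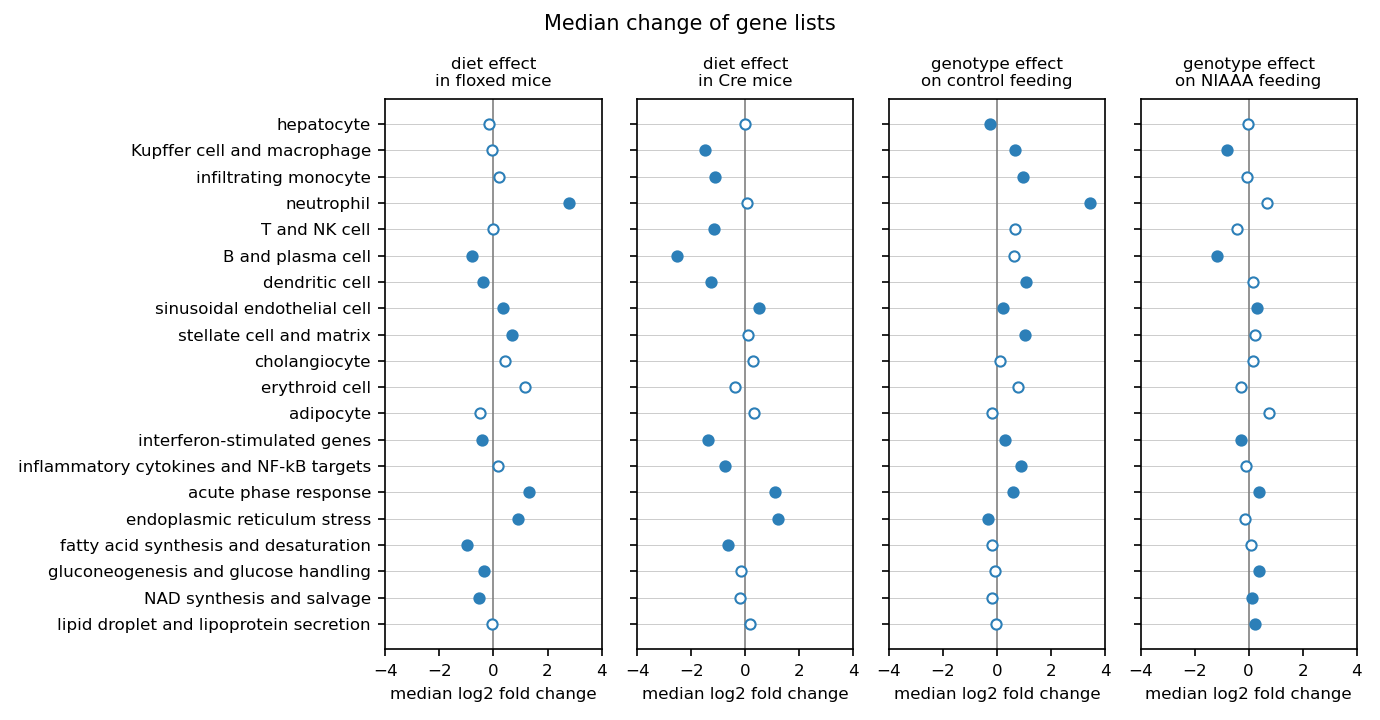
Median log2 fold change of the tested members of 20 gene lists (12 sets of cell type markers above, 8 pathways below) in the 4 comparisons of 2 groups; filled points have a camera adjusted p under 0.05 at the preset correlation of 0.01. B and plasma cell markers lie at −2.53 for the diet in Cre mice and at −0.79 in floxed mice, and none of the filled points held with an estimated correlation.

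On control feeding (LKO-NC against FLOX-NC), the genotype comparison asked how Cre mice differ from floxed mice without ethanol. Cre mice differ in the cre transgene as well as in Lpcat3, and no group carried cre alone. Neither genotype comparison can therefore tell a loss of Lpcat3 from an effect of cre. Camera called several lists of matrix and immune markers at the preset correlation, and 2 single genes were called. All 17 stellate cell and matrix genes had positive values (median 1.03); 0 were called, and the collagen genes Col1a1 (1.68, SE 0.419) and Col4a1 (1.23, SE 0.294) rose when adjusted over the list alone (camera adjusted p = 3.05e-09; adjusted p = 0.674 with an estimated correlation). Dendritic cell markers had a median of 1.07 with 0 called and 4 higher when adjusted over the list alone, among them H2-Eb1 (1.42, SE 0.29), and infiltrating monocyte markers a median of 0.96 with 0 called and 5 higher when adjusted over the list alone, among them Cx3cr1 (1.86, SE 0.463) (camera adjusted p = 6.8e-06 and 2.65e-05; adjusted p = 0.674 for both with an estimated correlation). Cytokine and NF-kB target genes had a median of 0.90 with 0 called and 2 higher, Nfkb2 and Relb, when adjusted over the list alone, and neutrophil markers a median of 3.44 with 0 called and 4 higher, among them S100a8 (4.98, SE 1.02), when adjusted over the list alone (camera adjusted p = 1.52e-07 and 5.87e-07; adjusted p = 0.674 for both with an estimated correlation). Male-biased liver genes had a median of −1.17, or −1.15 with 1 member at its bound, with 0 called in either adjustment (camera adjusted p = 2.05e-10; adjusted p = 0.684 with an estimated correlation). Without LKO-NC replicate 1 these medians were 0.43 for dendritic, 0.41 for monocyte and −0.76 for male-biased genes, and 0.19 for NF-kB targets and −0.16 for neutrophil markers, of which the last 2 lost their calls (camera adjusted p = 0.163 and 0.853). Without LKO-NC replicate 2 they were 1.46 for monocyte and −2.09 for male-biased genes. Hepatocyte markers had 10 of 13 negative values (median −0.26) with 0 called in either adjustment (camera adjusted p = 0.0317; adjusted p = 0.722 with an estimated correlation). LKO-NC replicate 1, the library with 25.3% mitochondrial counts, had the lowest mean log2 CPM of these markers in this comparison, 11.35, against 11.87 to 11.93 in the 4 other libraries. Without it the median was 0.03 (camera adjusted p = 0.855), without LKO-NC replicate 2 it was −0.69, and without FLOX-NC replicate 3 the call was lost (−0.31, 0.0797). Sinusoidal endothelial markers had 14 of 14 positive values (median 0.23) with 0 called in either adjustment (camera adjusted p = 0.0131; adjusted p = 0.722 with an estimated correlation). Their median was 0.51 without LKO-NC replicate 1, and the call was lost without LKO-NC replicate 2 (−0.05, 0.576) or FLOX-NC replicate 2 (0.20, 0.0588).

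The 2 genes called on control feeding by edgeR were Fgf2 and Jade1. In that fit 1240 genes had an unadjusted p under 0.05, where 951 would be expected by chance. This number was 780, 917 and 1073 without FLOX-NC replicates 1, 2 and 3. Genes are not independent, so such a number can lie above or below its expectation without an effect of genotype. Fgf2, a fibroblast growth factor gene on chromosome 3 (37348346 to 37410108, + strand), was measured at 6.15 ± 1.63 CPM in FLOX-NC and 0.0966 ± 0.0777 CPM in LKO-NC (log2 fold change −5.97, SE 0.619, edgeR adjusted p = 0.00714). It overlaps Nudt6 on the opposite strand by 5199 bases, and counting by strand is not stated, so this value is uncertain. Jade1, a subunit of a histone acetyltransferase complex, was measured at 4.49 ± 1.39 and 31.4 ± 14.8 CPM (2.80, SE 0.336, edgeR adjusted p = 0.0174). On FPKM values neither was called (Fgf2 −0.64, limma adjusted p = 0.479; Jade1 1.33, limma adjusted p = 0.376), and limma voom did not call Fgf2 (−5.97, adjusted p = 0.296). Jade1 lost its call without FLOX-NC replicate 1, 2 or 3 (edgeR adjusted p = 0.146, 0.104 and 0.117) and without LKO-NC replicate 1 (0.088). The count was 1 without each FLOX-NC library in turn, 5 without LKO-NC replicate 1 and 21 without LKO-NC replicate 2, and it was 56 by DESeq2, 2 by limma voom and 0 by limma on FPKM.

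On NIAAA feeding (LKO-ALD against FLOX-ALD), the comparison closest to the question in the title, no single gene passed in edgeR. Lpcat3 had the smallest adjusted p (0.132). In the lipid droplet and lipoprotein secretion list, 19 of 25 values were positive (median 0.25) with 0 called; the lipid droplet gene Cidec was measured at 3.21 ± 2.20 CPM in FLOX-ALD and 31.6 ± 22.9 CPM in LKO-ALD (3.29, SE 0.649) and, with Apoa4 (1.66, SE 0.444), rose when adjusted over the list alone. The NAD list had a median of 0.11 with 0 called and 4 higher when adjusted over the list alone, Nampt, the tryptophan-degrading enzyme gene Tdo2 (1.63, SE 0.458), Kmo (0.78, SE 0.207) and Slc25a51 (1.40, SE 0.372), the mitochondrial NAD carrier. All 11 B and plasma cell markers had negative values (median −1.17, or −0.72 without FLOX-ALD replicate 1 and LKO-NC replicate 1 together), with 0 called in either adjustment. Interferon-stimulated genes had a median of −0.30 with 0 called and 2 lower, Ifi27l2a and Rsad2, when adjusted over the list alone. Kupffer cell markers had a median of −0.81 with 0 called in either adjustment. Camera called these lists (adjusted p = 0.00151, 0.0255, 0.000337, 0.000337 and 0.000453 in this order), and none held (adjusted p = 0.844, 0.844, 0.791, 0.844 and 0.844 with an estimated correlation). They were among 16 of the 45 lists that camera called here. The others included the acute phase response, the integrated stress response and male- and female-biased liver genes. The male- and female-biased lists lost their call without FLOX-ALD replicate 1 (camera adjusted p = 0.382 and 0.304).

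Single libraries decided much of this comparison. Without FLOX-ALD replicate 1, the Kupffer cell median was −0.34 (camera adjusted p = 0.333) and the interferon median −0.17. Without FLOX-ALD replicate 2 the lipid droplet median was 0.38, and without FLOX-ALD replicate 3 it was 0.06 and lost its call (camera adjusted p = 0.251). Without LKO-ALD replicate 1 the medians were −0.44 for Kupffer cell and 0.15 for lipid droplet genes, without LKO-ALD replicate 2 −0.71 for interferon-stimulated genes, and without LKO-ALD replicate 3 −0.13 for interferon and 0.38 for lipid droplet genes. The NAD list lost its call without FLOX-ALD replicate 1 or 3 (median 0.09 and 0.19) and without LKO-ALD replicate 1 or 2 (0.23 and −0.04), and its median was 0.19 without LKO-ALD replicate 3. Beside the count of 0 by edgeR, 1531 genes had an unadjusted p under 0.05 (951 expected by chance). Without single libraries this number ran from 979 (without LKO-ALD replicate 1) to 2259 (without FLOX-ALD replicate 2). DESeq2 called 116, and limma voom and limma on FPKM called 0. Leaving out FLOX-ALD replicates 1, 2 and 3 gave 1, 6 and 3 genes, and leaving out LKO-ALD replicates 1, 2 and 3 gave 0, 3 and 0.

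The interaction asked whether Cre mice answered the diet differently from floxed mice. Fgf2 was the only gene past the edgeR threshold (5.90, SE 0.707, edgeR adjusted p = 0.0351), with the same uncertainty about Nudt6. It rested on the low LKO-NC counts and stayed short of the threshold without FLOX-NC replicate 1, 2 or 3 (adjusted p = 0.0791, 0.143 and 0.152), LKO-NC replicate 2 (0.0516) and LKO-ALD replicate 1, 2 or 3 (0.109, 0.117 and 0.0509). Kupffer cell markers had a median interaction of −1.43 (0 called; Cd68 and Clec4f lower when adjusted over the list alone), and B and plasma cell markers −1.78 (0 called; Cd22 and Ighd lower when adjusted over the list alone). Interferon-stimulated genes had −0.57 (0 called; 3 lower when adjusted over the list alone, among them Ifi27l2a at −2.16, SE 0.492). Camera called the 3 lists (adjusted p = 1.82e-06, 0.000736 and 4.46e-05), and none held (adjusted p = 0.724 for each with an estimated correlation). The Kupffer cell median was −0.83 without FLOX-ALD replicate 1, the B cell median −0.65 without LKO-NC replicate 1, and the interferon median −0.96 and −0.36 without LKO-ALD replicates 2 and 3. With both FLOX-ALD replicate 1 and LKO-NC replicate 1 left out, a choice made after seeing the data, the 3 medians were −0.42, −0.66 and −0.14 and none was called. In total 1781 genes had an unadjusted p under 0.05 in edgeR (951 expected by chance). This number was 1169, 1356 and 1642 without FLOX-NC replicates 1, 2 and 3. It was 1972, 2297 and 1695 without FLOX-ALD replicates 1, 2 and 3, and 1251, 1631 and 2009 without LKO-ALD replicates 1, 2 and 3. DESeq2 called 72, and limma voom and limma on FPKM called 0. The count was 0 without each FLOX-NC or LKO-ALD library in turn, 5 and 6 without LKO-NC replicates 1 and 2, and 3, 8 and 3 without FLOX-ALD replicates 1, 2 and 3.

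Across the 19014 genes, which are not independent replicates, the diet effects of the genotypes correlated weakly (Pearson 0.223, Spearman 0.281). They shared 15 lower and 2 higher genes, where independent lists would share 0.219 and 0.0265, and 0 genes were called in opposite directions. The shared genes included Lpcat3, Ighm, Zfand4, Cabyr, H2-Q1, Tuba1c and Ildr2. Over the 42 genes called in floxed mice, 41 had the same sign in Cre mice, with a slope of 0.463 of the Cre on the floxed effect. Over the 182 genes called in Cre mice, 165 had the same sign in floxed mice, with a slope of 0.379. Genes were called for their size in one of the effects, which lowers such slopes. The diet effect in floxed mice and the genotype effect on NIAAA feeding share the FLOX-ALD libraries. Their correlation was −0.385, against −0.501 in 20 simulations with unchanged groups, and their covariance was −0.39 against −0.32 simulated, a difference of −0.0697. Leaving out 1 library moved that covariance to between −0.753 and −0.309.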

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

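The tests on sex-specific transcripts, on Fgf2 with Nudt6, on transcript assignment with a count minimum, and on the immune gene lists were chosen only after these results were seen; the test on transcript assignment over all assessed genes and the splits of the samples were planned.

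The interaction of diet and genotype passed its test for Fgf2 (5.90 on the log2 scale) and, in camera with the preset correlation, for 15 gene lists (adjusted p from 6.29e-11 to 0.0276), none of which held (adjusted p = 0.724 or more with an estimated correlation). Lower interaction medians were measured for Kupffer cell (−1.43), infiltrating monocyte (−1.33), neutrophil (−2.00), B and plasma cell (−1.78), dendritic cell (−0.65) and stellate cell (−0.61) markers, for NF-kB targets (−1.16), interferon-stimulated genes (−0.57) and female-biased liver genes (−5.09). Higher medians were measured for NAD synthesis (0.26), gluconeogenesis (0.39), periportal (0.38), urea cycle (0.38), oxidative phosphorylation (0.33) and male-biased liver genes (1.62). Without the members that had a count of 0 in a whole group, the medians were −2.16 for neutrophil, −2.52 for female-biased and 1.58 for male-biased genes. Without LKO-NC replicate 1, 9 of these lists lost their call, with medians of −0.53 for monocyte, 0.39 for neutrophil, −0.27 for dendritic and −0.41 for NF-kB genes and of 0.066 for NAD, 0.20 for gluconeogenesis, 0.26 for periportal, 0.15 for urea cycle and −0.0693 for oxidative phosphorylation genes, while B cell markers stood at −0.65 and stayed called. Without LKO-NC replicate 2 the medians were −1.06 for dendritic, −1.11 for stellate, 0.76 for NAD, 0.735 for gluconeogenesis, 0.64 for urea cycle, 0.74 for oxidative phosphorylation and 2.66 for male-biased genes, and female-biased genes (−5.63) lost their call. Without FLOX-ALD replicate 1 they were −0.83 for Kupffer cell and −0.94 for stellate genes, and female-biased (−0.75) and neutrophil genes (−1.73) lost their call. Calls were also lost for stellate (−0.23) and periportal genes (0.41) without FLOX-ALD replicate 2, for neutrophil (−2.02) and oxidative phosphorylation genes (0.12) without FLOX-ALD replicate 3, and for neutrophil genes (−1.79) without FLOX-NC replicate 3. They were lost for neutrophil (−2.14), stellate (−0.24), NAD (0.20) and periportal genes (0.20) without LKO-ALD replicate 2, and for female-biased genes (−4.93) without LKO-ALD replicate 3. Medians that moved with their call kept were urea cycle (0.22) without FLOX-ALD replicate 3, oxidative phosphorylation (0.216) without FLOX-NC replicate 3, stellate (−0.33) without LKO-ALD replicate 1, interferon-stimulated (−0.96) without LKO-ALD replicate 2, and dendritic (−1.08), stellate (−1.08) and interferon-stimulated genes (−0.36) without LKO-ALD replicate 3. With FLOX-ALD replicate 1 and LKO-NC replicate 1 both left out, 13 of the 15 lists lost their call.

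FLOX-ALD replicate 1, labelled male, carried sex-specific transcripts of the other kind. A male liver mixed with female tissue is argued against by the 4 Y-linked genes, which stood at 0% of the lowest other library. A female-type pattern induced in a male liver is argued against by Xist, which was 262-fold over the highest other library. A sample of a female animal under a male label is consistent with 82% of the sex-biased list members having their most female value in this library, where 9.09% would be expected by chance. The diet comparison of floxed mice, the genotype comparison on NIAAA feeding and the interaction therefore carry a candidate difference of sex in 1 of 3 FLOX-ALD libraries.

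Of 182 diet calls that could be assessed (42 could not), 6 (3.30%) coincided with a shift in the mean length of the assigned transcripts over 0.5 on the log2 scale, against 1.01% of uncalled genes of like expression, a ratio of 3.26 (exact 95% interval 1.21 to 6.97). Among genes with at least 20 counts in every library, a limit that also takes out genes that fell to few counts, there were 4 of 171 calls and a ratio of 2.99 (0.818 to 7.50); the limit leaves out Fgf2, whose shift of 4.46 rests on LKO-NC counts of 7 and 2. The length shift had the sign of the count change in 4 of the 6 and in 2 of the 4, so assignment of reads between transcripts stays open as a source of a few calls, such as Jade1 (shift 0.896), and moves between transcripts of like length, such as those of Fbf1 (5223 and 5252 bases), are not seen by the test. The length shift of Lpcat3 was 0.452 for the diet in Cre mice, short of the 0.5 used here. For the low Fgf2 counts of LKO-NC, the sum of Fgf2 and its antisense neighbour Nudt6 changed by −0.477 (SE 0.286), where loss of Fgf2 alone would give −0.973. A loss of Fgf2 transcripts and a transfer of its reads to Nudt6 cannot be told apart, because the sum lies within 2 SE of both 0 and that value.

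Camera called 7 immune lists lower on the NIAAA diet in Cre mice (interferon-stimulated, NF-kB target, B cell, Kupffer cell, dendritic, monocyte, and T and NK genes), with a median of −1.22 over their 125 members. A smaller share of hepatocyte RNA in LKO-NC was tested with sinusoidal endothelial markers. Their median was 0.51 (lower quartile 0.0401), while the upper quartile of the immune members was −0.40. The endothelial median was 0.21 without LKO-NC replicate 1, and 0.27 and not called by camera without LKO-ALD replicate 3. The test cannot decide the question, because a rise with the diet could hide a lower share. In floxed mice these markers also had positive medians for the diet (0.14 to 0.53 without single libraries). Hepatocyte markers had a mean log2 CPM of 11.35 in LKO-NC replicate 1, the lowest of the 11 libraries, and of 11.89 in LKO-NC replicate 2. In LKO-ALD it was 11.85, 11.89 and 11.66. LKO-NC replicate 1 alone stays open as a source, since without it the median was −0.788 and 4 of the 7 lists stayed called, while NF-kB (0.38), monocyte (−0.07) and T and NK genes (−0.86) lost their call (camera adjusted p = 0.285, 0.414 and 0.0932). A lower content of these immune cells or a lower expression in them also remain open, and no list held with an estimated correlation.

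For the 42 genes called between FLOX-ALD and FLOX-NC, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and the highest of the others gave 1. With 10 splits the share cannot be under 0.05. For the 0 genes called between LKO-ALD and FLOX-ALD, all 10 splits gave as many, which a count of 0 fixes in advance, so this says nothing about chance. The highest of the others gave 99, with FLOX-ALD replicates 1 and 3 and LKO-ALD replicate 3 on one side. That split is given for its count, and what sets it apart was not tested.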

How the results depend on the processing

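Leaving out FLOX-ALD replicate 1 and LKO-NC replicate 1 together, leaving out mitochondrially encoded genes, and all settings of the relation between the diet effect in floxed mice and the genotype effect on NIAAA feeding were chosen after the data were seen. Where no reason is given, the cause was not tested.

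The counts of called genes depended on the test and the libraries. For the diet in floxed mice, against 42, the count was 4 at an adjusted p under 0.01, 128 without a filter, 20 without the robust fit, 595 by DESeq2, 64 by limma voom, 6 in a fit of only the 2 groups, 18 without both libraries, and 2 to 146 without single libraries. For the diet in Cre mice, against 182, it was 8, 404, 109, 1470, 647, 23, 29 and 6 to 138 in the same order. For the genotype on control feeding, against 2, it was 1 at an adjusted p under 0.01, 7 without a filter, 56 by DESeq2, 0 by limma on FPKM, 5 in a fit of only the 2 groups, 6 without both libraries and 1 to 21 without single libraries. For the genotype on NIAAA feeding, against 0, it was 3 without a filter, 116 by DESeq2, 3 without both libraries and 0 to 6 without single libraries. For the interaction, against 1, it was 0 at an adjusted p under 0.01, with upper quartile factors, with at least 1 CPM in 3 libraries, without the robust fit, by limma voom and by limma on FPKM, 5 without a filter, 72 by DESeq2, 6 without both libraries and 0 to 8 without single libraries. A stricter threshold lowers the count by construction. Of the called genes, DESeq2 shared 42 of 42 for the diet in floxed mice and 181 of 182 in Cre mice, and limma on FPKM shared 24 and 84. Upper quartile factors moved the median of all genes to −0.11 for the diet in Cre mice and to −0.17 for the interaction.

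The replicate block and its check used the numbers in the sample titles, which 5 pairs of control and NIAAA libraries of a genotype share; LKO-NC replicate 2 is so paired with LKO-ALD replicate 3. Libraries of equal title number did not deviate together, with correlations of −0.0505 to 0.0778 over 5 pairs, 0 of them over 0.1, and 1 pair correlating best with its own number. The check gave no sign of pairing but cannot exclude it, because deviations from the mean of 2 LKO-NC libraries mirror each other. The block adds a term per title number, which leaves fewer than the 7 residual degrees of freedom. Under it LKO-ALD replicate 2, without a control library of its number, adds nothing to the diet effect. Counts with and without a block are therefore not on the same footing. With a replicate block the counts were 12 for the diet in floxed mice, 7 in Cre mice and 0 for the interaction, of which 3 and 4 were shared with the fit without a block for the 2 diet effects. Lpcat3 under the block was −1.40 (adjusted p = 0.1) in floxed and −1.68 (0.0732) in Cre mice.

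Lpcat3 kept its direction in every setting for the diet and genotype effects. The diet effect in floxed mice lost its call by limma on FPKM (−1.32, adjusted p = 0.0529), in a fit of only the 2 groups (−1.39, 0.0591) and without both libraries (−1.40, 0.101), and ran from −1.52 to −1.24 without single libraries. The diet effect in Cre mice lost it in a fit of only the 2 groups (−1.48, 0.0815) and without both libraries (−1.63, 0.071), and ran from −1.71 to −1.28. The genotype difference was called without a filter and by DESeq2, at −1.56 and −1.55 on control and −1.63 and −1.64 on NIAAA feeding, and ran from −1.73 to −1.39 on control and −1.86 to −1.49 on NIAAA feeding without single libraries. On FPKM values it was −0.88 and −1.40, not called. The interaction of Lpcat3 ran from −0.29 to 0.0913 without single libraries and from −0.52, by limma on FPKM, to 0.0913 over all settings. The diet difference of Nampt in Cre mice ran from −0.0755 to 0.44 without single libraries.

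At the preset correlation of 0.01, camera called 24 of the 45 lists for the diet in floxed mice and 17 for the diet in Cre mice. It called 18 for the genotype on control feeding, 16 for the genotype on NIAAA feeding and 15 for the interaction. The estimated correlations had medians of 0.274 to 0.289 over the lists of a comparison. With an estimated correlation 0 lists were called in each of the 5 comparisons. Fry called 1 for the diet in floxed mice (LXR targets, fry adjusted p = 0.0384). It called 1 for the diet in Cre mice (B and plasma cell markers, 0.00734) and 0 in the others. Without single libraries, camera called 11 to 23 lists for the genotype on control feeding, 9 to 24 for the genotype on NIAAA feeding and 8 to 24 for the interaction, and 5 for the interaction without both libraries. Some list medians changed sign. For the diet in Cre mice, oxidative phosphorylation ran from −0.19 to 0.55 without single libraries and was −0.19 without both. For the genotype on control feeding, endoplasmic reticulum stress ran from −1.02 to 0.16 (0.16 without both) and oxidative phosphorylation from −0.63 to 0.0574 (0.0577). The urea cycle median there stayed negative, from −0.44 to −0.00324 (−0.00294 without both), while its camera direction turned to higher, not called, without LKO-NC replicate 1 or both libraries. For the genotype on NIAAA feeding, fatty acid oxidation ran from −0.0688 to 0.41, the integrated stress response from −0.10 to 0.87, the acute phase response from −0.17 to 1.42, male-biased genes from −0.13 to 1.01 (−0.14 without both) and female-biased genes from −4.05 to 0.67 (0.60). For the interaction, neutrophil markers ran from −3.00 to 0.39 (0.40 without both) and oxidative phosphorylation from −0.0693 to 0.74.

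The correlation of the 2 diet effects was 0.354 with at least 1 CPM in 3 libraries, 0.145 without both libraries and 0.124 to 0.241 without single libraries. The covariance of the diet effect in floxed mice with the genotype effect on NIAAA feeding was −0.143, −0.900 and −0.753 to −0.309 in the same settings.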

Other observations

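The genes in the next paragraph and the test on genes near Lpcat3 were chosen only after the values were seen.

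Hdc, which encodes histidine decarboxylase, fell on the NIAAA diet in both genotypes (log2 fold change −1.78, SE 0.190, edgeR adjusted p = 0.00508 in floxed mice; −1.67, SE 0.204, 0.00842 in Cre mice). Pcyt2, an enzyme gene of phosphatidylethanolamine synthesis, fell in Cre mice (−1.46, SE 0.307, edgeR adjusted p = 0.0488), and its value in floxed mice was −0.19 (SE 0.279, 0.84; interaction −1.28, SE 0.416, 0.498). Nr0b2, which encodes the bile acid-induced repressor SHP, fell in Cre mice (−2.86, SE 0.509, edgeR adjusted p = 0.0345), and its value in floxed mice was −1.94 without passing (SE 0.464, 0.13). The imprinted transcript H19 fell in Cre mice (−4.44, SE 0.788, edgeR adjusted p = 0.0318) and was 3.22 higher in LKO-NC than in FLOX-NC without passing the test (SE 0.748, 0.571). Klf10, a zinc finger gene induced by TGF-beta, fell in floxed mice (−1.27, SE 0.230, edgeR adjusted p = 0.0498) and had an interaction of 2.19 that did not pass (SE 0.349, 0.164). On NIAAA feeding, Gpcpd1, which encodes a glycerophosphocholine phosphodiesterase, had a genotype difference of 1.98 that did not pass the test (SE 0.409, edgeR adjusted p = 0.341).

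In floxed mice the ethanol and acetaldehyde oxidation list had 12 of 15 negative values on the NIAAA diet (median −0.48), with 0 called, and 1 higher (Acss3) and 4 lower (Cat, Aldh7a1, Acss2 and Adh4) when adjusted over the list alone (camera adjusted p = 0.0044; adjusted p = 0.535 with an estimated correlation). Without FLOX-ALD replicate 3 the median was −0.33 and the call was lost (camera adjusted p = 0.0693). Circadian clock genes had a median of −0.58 with 0 called and 4 lower when adjusted over the list alone, among them Nr1d1 (−1.31) and Ciart (−1.89) (camera adjusted p = 0.00044; adjusted p = 0.327 with an estimated correlation). That median was −0.35 without FLOX-ALD replicate 1.

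A hypothesis was that the genotype comparisons carry differences of genes brought along with the targeted Lpcat3 allele from another mouse strain. Of 228 tested genes within 10 megabases of Lpcat3, 7.02% had an unadjusted p under 0.05 on control feeding, against 6.52% of all genes, and 3.95% on NIAAA feeding, against 8.05%. The larger of the 2 ratios was 1.08. Floxed and Cre mice both carried the floxed gene, so genes brought along with it could be shared by both genotypes. The test therefore cannot decide the question, and genes near the cre transgene were not tested.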
